A study of Mus musculus with 8 samples.

How the data were processed

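RNA was measured in 8 libraries of organoids from embryonic mouse hindstomach epithelium, 4 labelled control (genotype Shh-Cre) and 4 labelled YAP5SA, sequenced from total RNA as 150 bp paired-end reads, per the labels' protocols. The values used are the deposited read counts per gene, whole numbers that were not normalized. Per the submitters' processing notes, the tools were cutadapt, HISAT2 2.0.1 and HTSeq 0.6.1, and the genome build was mm9. The annotation release, the counting options and the handling of strand are not given in the sources used here. Several gene symbols in the table are newer than that build, so no coordinates are printed, and the chromosome of each gene was taken by its symbol from the GENCODE M21 mouse annotation, which matched 13666 of the 14058 tested genes. Reads of overlapping or antisense genes cannot be told apart without strand, and values of genes with near-identical copies (Hspa1a and Hspa1b, the Sprr, Krt6 and lysozyme genes, Oas1a, the actins, and Y-linked genes with X-linked homologues) are uncertain to the extent that reads were shared or discarded.

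The table has 56691 rows. The 2639 rows without a gene name, which held 0.190% to 0.221% of the counts of a library, were left out of library sizes and tests, and 959 rows that share 77 symbols were summed by symbol, which left 53170 named genes, 27156 of them with a count in any library. Total counts per library were between 13672268 and 19710648. Genes were kept by edgeR's filterByExpr with the group and its defaults (a minimum count of 10 and a minimum total of 15), which left 14058. Counts were normalized by TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest), with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg over the tested genes, with calls at an adjusted p under 0.05. Fold changes are YAP5SA over control. Standard errors are the log2 fold change divided by the square root of its F value. The common biological coefficient of variation was 7.97%. CPM use the TMM-scaled library sizes of the tested genes. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A group with 0 counts was set to a floor of 3 counts over the group, and for 1 to 3 counts the ratio of pooled levels was given with an exact 95% interval.

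Gene lists were fixed before the data were examined. The 33 lists are YAP/TAZ target genes, Hippo pathway components, pit (surface mucous) cells, neck and gland mucous cells, chief cells, parietal cells, enteroendocrine cells, tuft cells, gastric stem and progenitor cells, gastric epithelial transcription factors, fetal-like and regenerative epithelium, squamous forestomach epithelium, intestinal epithelium, pancreatic acinar cells, cell cycle, Wnt target genes, Notch pathway, TGF-beta and BMP targets, epithelial-mesenchymal transition, epithelial junctions, actin cytoskeleton and focal adhesion, p53 targets and apoptosis, unfolded protein response and stress, immediate early genes, interferon response, cholesterol synthesis, glycolysis and hypoxia, and mesenchymal, endothelial, immune, enteric neural, mesothelial and erythroid cells. Some genes stand in more than 1 list (Aqp5, Axin2, Cd44, Krt19, Lgr5, Msln, Sox9 and Tnfrsf19). The 27 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 27 lists. Camera with an estimated correlation and fry were alternatives. Principal components were computed from log2 CPM of the 500 most variable genes, centred and not scaled.

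The genes named were chosen by a rule fixed before the data were examined, namely Yap1, Ccn1, Ccn2 and Ankrd1; the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with an average log2 CPM of at least 3 and no overlap between groups, passing over unnamed gene models; up to 4 members with the smallest adjusted p of each list that camera called or that had at least 3 called members; the most abundant marker of each other cell type; and members of a list that go against its main direction. Other members named as examples (Bhlha15, Xbp1, Bax, Atp4a, Kcnq1, Muc5ac, Gkn3, Muc6, Muc4, Cd44, Ehf, Clu, Isl1, Ddc, Tek, Tie1, Csf1r, Uchl1, and the basal keratin and Cdx genes) were chosen after their values were seen. Some genes that the rule takes are not reported here.

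The test was checked on simulated counts drawn from the means, library sizes and dispersions of these libraries, in which 200 genes were changed by known folds before filtering. Among the 13879 genes tested there, it recovered 73.3% of the 1.5-fold, 85.7% of the 2-fold and 100% of the 4-fold changes, and 15 unchanged genes were called (8.02% of its calls). That share is above the one that an adjusted p of 0.05 aims at. The simulated changes were fewer than the 6899 genes changed in the data and at most 4-fold. The simulation therefore does not show how the test behaves when so many genes change. Replicates were compared by a chi-square statistic over genes, and no pair of libraries agreed within sampling noise. The alternatives were 3 other normalizations, 2 other filters, DESeq2 1.42.0, limma-voom with and without sample quality weights, the sample number as a block, a stricter threshold, leaving out each library in turn, and, added after the data were examined, leaving out X- and Y-linked genes. Within each group of 4, a value was singled out where its gap to the nearest other library exceeded Dixon's 95% criterion.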

Results

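Bulk RNA sequencing was carried out on organoids grown from the epithelium of the glandular stomach (hindstomach) of mouse embryos at embryonic day 18.5, after 5 days in growth medium. The series holds 8 libraries in 2 groups. The 4 control libraries carry Shh-Cre alone, a recombinase expressed in foregut epithelium, and the 4 YAP5SA libraries carry Shh-Cre together with the YAP5SA transgene, an active form of YAP, the transcriptional coactivator that the Hippo kinases restrain. Total counts per library ran from 13672268 (control 4) to 19710648 (control 3), and between 19831 and 20555 named genes had at least 1 count. Mitochondrial genes took 4.38% to 5.18% of the counts. Levels are given in CPM, counts scaled to a common library size, as mean ± SD of the 4 libraries of a group, and fold changes compare YAP5SA with control. The labels do not say whether the libraries of a group come from separate embryos or cultures, so the p-values measure only the spread between these libraries, which may be technical. Organoids in differentiation medium and single-cell data of this study were not analysed here.

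The comparison asked how gene expression differs between the organoids labelled YAP5SA and those labelled control. The stomach genes Pgc and Cldn18 were nearly absent from YAP5SA organoids. Pgc, which encodes the digestive enzyme precursor progastricsin of chief cells, averaged 585.9 ± 65.2 CPM in controls and 1.08 ± 0.65 CPM in YAP5SA, and Cldn18, the tight junction claudin of stomach and lung epithelium, averaged 1353 ± 42 and 2.05 ± 1.31 CPM. Of 18 tested transcription factors of gastric epithelium, 11 fell, among them Gata5 (log2 fold change −8.74) and Hnf4a (−5.04), and 6 rose, among them Klf4 (2.48) and Ehf (1.71), and the list was not called by camera, a competitive test of a list against all other genes (adjusted p = 0.0582). Among genes outside that list, Krt4, a keratin of stratified and transitional epithelia, rose from 116.4 ± 23.5 to 951.0 ± 61.5 CPM, and Mmp14, a membrane-bound metalloproteinase, from 5.89 ± 1.40 to 159.3 ± 1.0 CPM. Of 25 cell cycle genes 19 rose, by less than 2-fold, and of 12 p53 target genes 11 fell, while the standard YAP targets went both ways. Camera called the cell cycle and p53 lists (adjusted p = 7.12e-05 and 0.000657), but not with an estimated correlation (adjusted p = 0.439 and 0.426 with an estimated correlation).

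**Figure D1:**
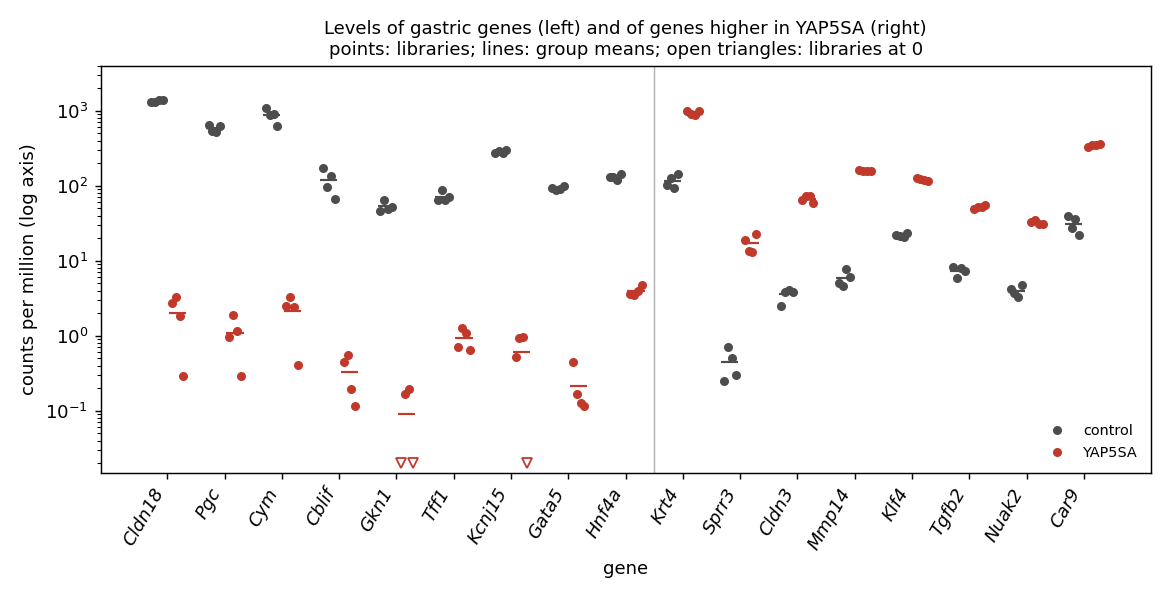
Levels in CPM of 9 gastric genes (left of the grey line) and 8 genes higher in YAP5SA (right) on a log axis, with 1 point per library, group means as lines and open triangles for libraries at 0 counts. For each of the 17 genes the 4 YAP5SA libraries lie entirely below or entirely above the 4 controls; Cldn18 averaged 1353 CPM in controls and 2.05 CPM in YAP5SA, and Krt4 averaged 116.4 and 951.0 CPM.

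Across the transcriptome, 6899 of 14058 tested genes (49.1%) changed at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 3315 higher and 3584 lower in YAP5SA. Scaling by library size alone turned this balance, to 3635 genes higher in YAP5SA and 3282 genes lower in YAP5SA. The larger changes were mostly decreases. Of the 1947 genes that changed at least 2-fold, 1207 were lower and 740 higher, and of those that changed at least 16-fold, 266 were lower and 71 higher. In 6422 genes (45.7%) the levels of the groups did not overlap, against 2.86% by chance if all 8 libraries were independent. Libraries of a group may share a source, in which case the share by chance is not known. The first principal component of the 500 most variable genes held 97.3% of the variance and separated the 4 controls from the 4 YAP5SA libraries.

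The groups also differed in sex. Xist, the RNA transcribed from the inactive X chromosome of female cells, ranged from 675.6 to 1049 CPM in the controls and from 0.41 to 2.76 CPM in the YAP5SA libraries. The Y-linked genes Eif2s3y, Uty, Kdm5d and Ddx3y averaged 101.6 ± 7.4, 42.4 ± 2.7, 59.2 ± 2.5 and 73.2 ± 3.4 CPM in YAP5SA, with between 2 and 6 counts each over all 4 controls. For Uty, with 2 counts in controls, the ratio of pooled levels was 1428 (95% counting interval 395 to 11790). Sex therefore coincided with genotype in all 8 libraries, and every difference described here, in every gene group, is at the same time a difference between male and female libraries. X- and Y-linked genes made up a small part of the calls, with 236 of 454 X-linked genes (52.0%), 5 of 8 Y-linked genes and 6503 of 13188 autosomal genes (49.3%) changed.

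**Figure D2:**
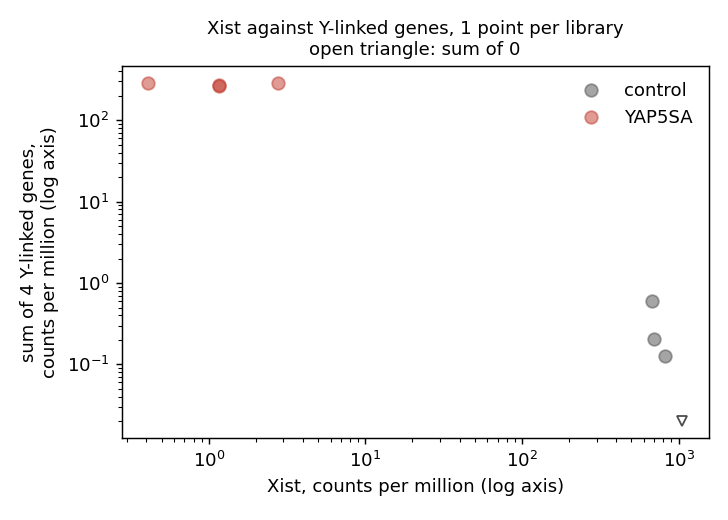
Xist (horizontal) against the sum of the Y-linked genes Eif2s3y, Uty, Kdm5d and Ddx3y (vertical), both in CPM on log axes, with 1 point per library and an open triangle for the library whose sum was 0. The 4 controls lie between 675.6 and 1049 CPM of Xist and the 4 YAP5SA libraries between 0.41 and 2.76 CPM, so that the groups occupy opposite corners.

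Mouse Yap1 itself did not pass the test, with 160.0 ± 7.2 CPM in controls and 153.3 ± 4.2 CPM in YAP5SA (log2 fold change −0.06 ± 0.05 SE, adjusted p = 0.339, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). The transgene may carry a human sequence that is not counted on the mouse gene, so Yap1 does not check the labels. Of 20 tested YAP/TAZ target genes, 10 rose, 7 fell and 3 did not pass the test. Nuak2, a kinase of the AMPK family, rose from 4.01 ± 0.66 to 32.6 ± 2.0 CPM, and the growth factor gene Tgfb2 rose from 7.40 ± 1.08 to 52.6 ± 2.3 CPM. The most used readouts did not follow. Ccn2 fell from 428.9 ± 32.3 to 206.6 ± 16.7 CPM (log2 fold change −1.05 ± 0.07 SE) and Ankrd1 from 22.7 ± 1.2 to 13.1 ± 4.6 CPM. Ccdc80 fell to 7.30 ± 0.79 from 39.5 ± 1.7 CPM, and Ccn1 had 80.5 ± 5.7 CPM in controls and 94.1 ± 20.6 CPM in YAP5SA (adjusted p = 0.205, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), a difference that passed without YAP5SA 3 (adjusted p = 0.0276, edgeR) and without a filter on low counts (0.0212). The list was not called by camera (adjusted p = 0.44, and 0.942 with an estimated correlation). Fry, which tests a list on its own, called it as higher in YAP5SA (adjusted p = 0.0231 by fry).

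**Figure D3:**
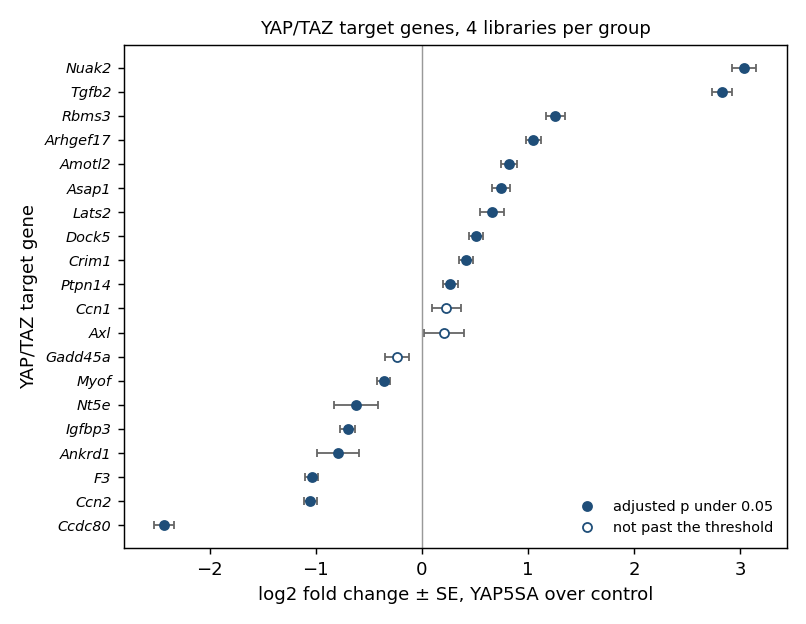
Log2 fold change (YAP5SA over control, horizontal) of the 20 tested YAP/TAZ target genes, with standard errors as bars, filled points for genes past an adjusted p of 0.05 and open points for the others. Nuak2 (3.04) and Tgfb2 (2.83) lie farthest to the right and Ccdc80 (−2.43) and Ccn2 (−1.05) farthest to the left.

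Among 22 components of the Hippo pathway, 6 rose, 4 fell and 12 did not pass the test. Adjusted over the list alone, 9 passed. Tead4, a DNA-binding partner of YAP, rose 2.91-fold, from 16 ± 1.6 to 46.3 ± 3.7 CPM. Amotl1, a junctional protein of the angiomotin family, fell from 57.4 ± 8.5 to 12.4 ± 3.1 CPM. The decreases of Mob1b (log2 fold change −0.50) and Vgll4 (−0.21) were small. Camera did not call the list (adjusted p = 0.507).

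Chief and parietal cell genes had the lowest median log2 fold changes of the 27 lists with at least 3 tested members, −7.82 and −4.89. These medians rest on 6 of 10 chief and 6 of 14 parietal cell genes. The untested members were nearly absent from the controls as well, at most 0.54 CPM (Kcne2). Among them were Lipf (0.19 CPM) and the proton pump gene Atp4b (0.05 CPM). Of 6 tested chief cell genes, 5 fell and none rose. Besides Pgc these were Cym (879.6 ± 191.4 to 2.16 ± 1.22 CPM), which encodes the milk-clotting protease chymosin, Cblif (118.4 ± 46.9 to 0.33 ± 0.21 CPM), which encodes intrinsic factor, Bhlha15 and Tnfrsf19 (910.5 ± 42.9 to 148.3 ± 6.4 CPM). Xbp1 did not pass the test (log2 fold change 0.10). The list was called by camera (adjusted p = 0.00109), but not with its correlation estimated from the data (adjusted p = 0.439 with an estimated correlation). Of 11 pit cell genes, 7 fell and 2 rose. Adjusted over the list alone, 10 passed. Gkn1 and Gkn2, the gastrokines secreted by surface mucous cells, fell from 53.5 ± 8.3 to 0.09 ± 0.10 CPM and from 50.5 ± 4.2 to 0.11 ± 0.06 CPM, and Tff1 and Ctse, a trefoil factor and the protease cathepsin E, fell by 6.24 and 5.91 on the log2 scale. Muc1, a membrane mucin, went the other way (341.0 ± 41.4 to 476.5 ± 11.8 CPM), and Muc5ac, the main mucin of mature pit cells, was at 0.72 ± 0.50 CPM in controls and 1.38 ± 0.50 CPM in YAP5SA. Camera called the pit cell list (adjusted p = 0.00742, and adjusted p = 0.426 with an estimated correlation).

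Of 6 tested parietal cell genes, 5 fell and 1 did not pass the test. Kcnj15 and Clic6, a potassium channel and a chloride channel protein, fell from 283.7 ± 12.1 to 0.61 ± 0.45 CPM and from 121.7 ± 8.8 to 0.28 ± 0.25 CPM, and the nuclear receptor gene Esrrg fell from 34.3 ± 3.0 to 0.10 ± 0.08 CPM. The proton pump gene Atp4a, low in both groups, fell from 8.21 ± 0.27 to 5.40 ± 1.33 CPM, and Slc26a9 fell as well, while the potassium channel gene Kcnq1 did not pass the test (log2 fold change 0.06). The list was called by camera (adjusted p = 0.00658, and adjusted p = 0.426 with an estimated correlation). Neck and gland mucous genes split, with 5 lower and 4 higher among 9 tested and no call by camera (adjusted p = 0.605). Gkn3 (319.4 ± 79.2 to 0.93 ± 0.43 CPM) and the gland mucin gene Muc6 (62.2 ± 21.5 to 0.34 ± 0.20 CPM) fell steeply, Glipr1 and the glutathione peroxidase gene Gpx2 fell by 3.13 and 1.30 on the log2 scale, and Wfdc2, Aqp5, Cd44 and Muc4 rose, Aqp5 from 320.5 ± 15.8 to 667.5 ± 63.7 CPM. Of the enteroendocrine genes only Isl1 and Ddc were counted often enough to test, and both fell. Among 5 tuft cell genes, 3 fell and 1 rose (camera adjusted p = 0.75). Dclk1 rose from 6.10 ± 1.26 to 12.8 ± 1.2 CPM, and the eicosanoid enzyme genes Alox5 and Ltc4s and the actin regulator gene Avil fell from low levels. Ltc4s no longer passed without control 3, YAP5SA 1 or YAP5SA 4 (adjusted p = 0.0562, 0.0561 and 0.0578, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), nor, at 0.0168 with all libraries, at a threshold of 0.01.

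Outside the lists, the largest decreases included Sec16b and A4gnt, the enzyme that caps gland mucin with N-acetylglucosamine. Both had 0 counts in all YAP5SA libraries. Against a floor of 3 counts over the group they were at least 479-fold and at least 393-fold lower. Cdhr2, a brush border cadherin, and Clps, the pancreatic colipase gene, had 1 and 2 counts in YAP5SA. Their ratios of pooled levels, control over YAP5SA, were 1841 (95% counting interval 330 to 72770) and 833 (230 to 6886). The largest increases on autosomes were Cyp2f2, a cytochrome P450 known from airway club cells (0.23 ± 0.12 to 181.8 ± 21.8 CPM), Bcat1, a branched-chain amino acid transaminase (0.30 ± 0.12 to 160.4 ± 8.2 CPM), Lypd2 (0.10 ± 0.10 to 25.1 ± 4.1 CPM) and the ephrin receptor gene Epha3 (0.12 ± 0.17 to 29.4 ± 1.1 CPM). These 4 genes had adjusted p between 1.39e-18 and 1.32e-13 (edgeR quasi-likelihood with Benjamini-Hochberg adjustment).

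Among 18 tested transcription factors of gastric epithelium, 11 fell, 6 rose and 1 did not pass the test. The GATA and HNF4 factors fell, Gata5 from 93.8 ± 4.6 to 0.22 ± 0.16 CPM and Hnf4a from 130.7 ± 9.4 to 3.95 ± 0.58 CPM, as did Foxa3 from 40.3 ± 2.1 to 0.79 ± 0.24 CPM. Klf4, a regulator of terminal differentiation in barrier epithelia, rose 5.59-fold (21.9 ± 1.0 to 122.0 ± 3.6 CPM) and Ehf rose from 305.1 ± 15.1 to 1002 ± 25 CPM. Camera did not call the list (adjusted p = 0.0582, and 0.491 with an estimated correlation). It did without control 2 or YAP5SA 1 (list: gastric epithelial transcription factors, adjusted p = 0.0421 and 0.0234 by camera). Stem and progenitor genes also parted, with 5 of 10 higher and 4 lower. Prom1 fell from 1670 ± 87 to 155.2 ± 9.0 CPM, and Lgr5, a receptor of gastric and intestinal stem cells, from 138.6 ± 11.9 to 72.2 ± 10.1 CPM, while Runx1 and Aqp5 rose 2.16-fold and 2.08-fold. The signs of the summary values of this list disagreed (median log2 fold change 0.21, mean −0.33), and camera did not call it (adjusted p = 0.93).

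Of 18 genes of fetal-like and regenerating epithelium, 14 fell, 3 rose and 1 did not pass the test (camera adjusted p = 0.00109, and adjusted p = 0.439 with an estimated correlation). Spp1, which encodes osteopontin, fell from 961.8 ± 30.8 to 13.8 ± 2.6 CPM, the alarmin gene Il33 from 1290 ± 104 to 106.1 ± 4.8 CPM, Sprr1a from 584.4 ± 55.9 to 25.0 ± 2.8 CPM, and the protease gene Ctsl from 668.0 ± 35.7 to 147.4 ± 18.1 CPM. Clu, the most abundant member, fell from 14400 ± 723 to 5435 ± 378 CPM. Ly6a, which encodes the surface antigen Sca-1, rose from 602.3 ± 75.5 to 1242 ± 102 CPM, and the EGF family ligand gene Ereg rose as well.

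**Figure D4:**
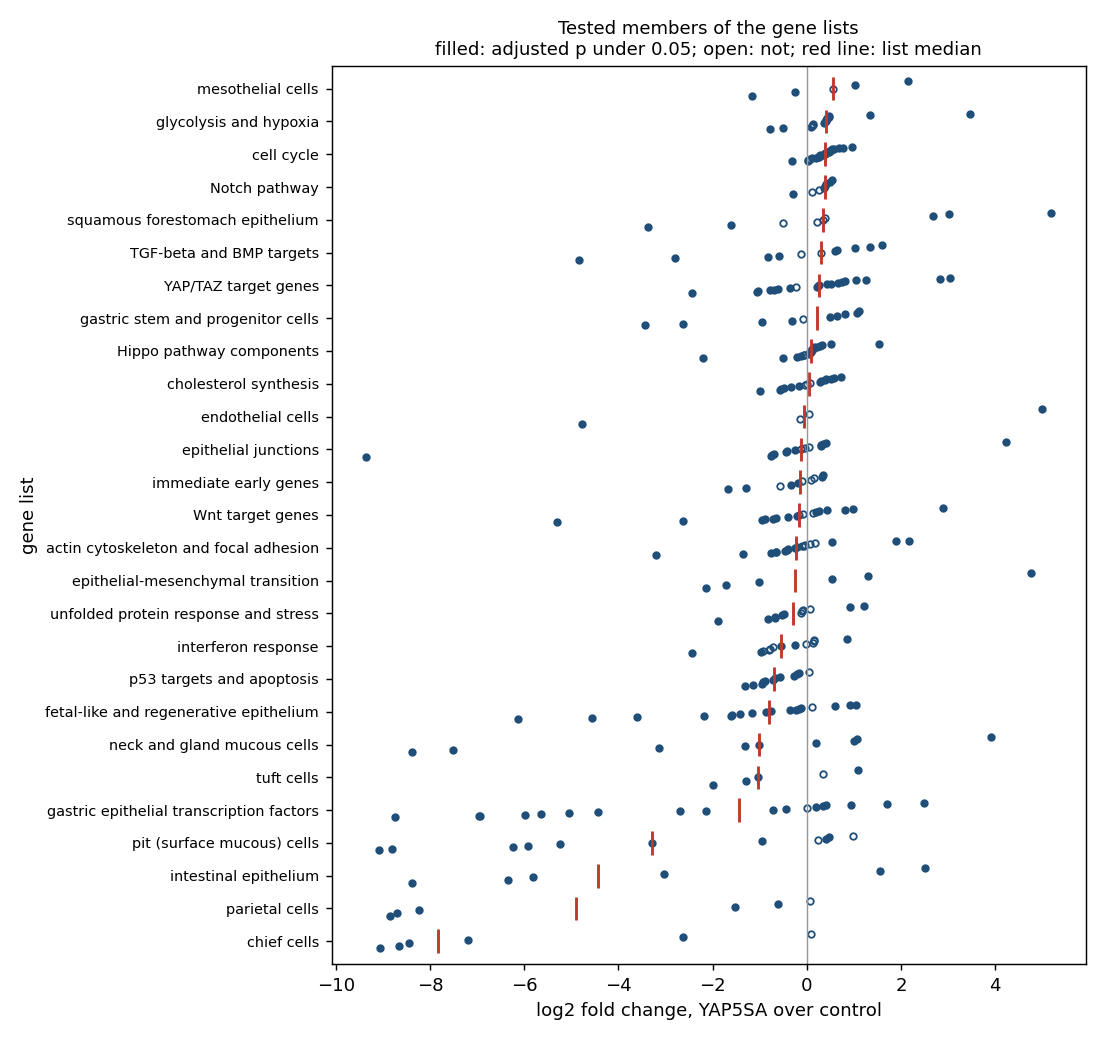
Log2 fold change (YAP5SA over control, horizontal) of each tested member of the 27 gene lists with at least 3 tested members, with filled points past an adjusted p of 0.05, open points for the others and the list median as a red line. Chief cell genes have the lowest median (−7.82), followed by parietal cell genes (−4.89); values of members with no counts in a group, such as Lyz1 and Pdx1, are fitted and not bounds.

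Markers of squamous forestomach went in both directions, with 3 of 9 tested genes higher, 2 lower and 4 not past the test (camera adjusted p = 0.507). Krt4 rose as given above, Sprr3, a cornified envelope protein gene, rose from 0.44 ± 0.21 to 17.1 ± 4.7 CPM, and Krt6a rose from 0.53 ± 0.33 to 3.27 ± 0.50 CPM, while Ivl (involucrin) fell from 31.4 ± 2.2 to 3.04 ± 0.28 CPM. The basal layer genes Krt5, Krt14 and Trp63 were too low to test in either group, at most 0.54 CPM. Of 6 tested intestinal genes, 4 fell and 2 rose (camera adjusted p = 0.0859), with a median log2 fold change of −4.43, or −4.41 with Lyz1 at its bound. Apoa1 fell from 375.1 ± 51.9 to 4.62 ± 0.99 CPM and the microvillus gene Vil1 from 99.9 ± 8.6 to 12.2 ± 3.0 CPM. Lyz1 had 0 counts in YAP5SA and was at least 55-fold lower, and Krt20 rose from 16.6 ± 2.5 to 94.9 ± 8.2 CPM. The intestinal regulators Cdx1 and Cdx2 had 0 CPM in both groups.

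Of 25 cell cycle genes, 19 rose, 1 fell (Ccne1, log2 fold change −0.32) and 5 did not pass the test (Mcm3, Mcm4, Mcm6, Mcm7 and Ccne2). The rises were below 2-fold: Ccnb2 1.95-fold (60.8 ± 7.6 to 119.1 ± 5.1 CPM), Cenpf 1.70-fold, Cdc20 1.49-fold and the proliferation marker gene Mki67 1.40-fold (460.8 ± 9.6 to 645.5 ± 12.8 CPM). The list had the lowest camera p (adjusted p = 7.12e-05), which was lost with an estimated correlation (adjusted p = 0.439 with an estimated correlation). Of 12 p53 target genes, 11 fell and Bax (log2 fold change 0.04) did not pass the test. Pmaip1, a BH3-only death gene, fell from 137.7 ± 12.2 to 55.5 ± 2.7 CPM, Trp53inp1 from 644.1 ± 45.4 to 291.5 ± 10.6 CPM, the cell cycle inhibitor gene Cdkn1a from 297.2 ± 12.8 to 157.1 ± 11.3 CPM and the X-linked receptor gene Eda2r from 90.3 ± 7.6 to 48.6 ± 4.6 CPM. Camera called the list (adjusted p = 0.000657, and adjusted p = 0.426 with an estimated correlation). Of 16 glycolysis and hypoxia genes, 10 rose and 2 fell (camera adjusted p = 0.00658, and adjusted p = 0.849 with an estimated correlation). Adjusted over the list alone, 13 passed. Car9, a hypoxia-induced carbonic anhydrase, rose from 31.3 ± 7.9 to 349.0 ± 17.2 CPM and Vegfa from 131.8 ± 23.0 to 332.8 ± 16.9 CPM, while the glycolytic enzyme genes Eno1 and Ldha rose 1.39-fold and 1.36-fold. Adm and Hk2 fell.

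The remaining pathway lists were not called by camera. Of 17 Wnt target genes, 8 fell and 6 rose (adjusted p = 0.717), with Nkd1 down from 16.5 ± 3.4 to 0.40 ± 0.23 CPM and Ephb3 up 1.98-fold. Of 8 Notch pathway genes, 5 rose and 1 fell (adjusted p = 0.0859), with Hes1, Jag2, Notch2 and Notch3 up by 1.45-fold, 1.42-fold, 1.32-fold and 1.31-fold. TGF-beta and BMP targets divided into 5 higher and 4 lower of 11 (adjusted p = 0.925), with Pmepa1 (11.1 ± 1.9 to 0.38 ± 0.16 CPM) and Skil down and Id2 up 1.56-fold. The median of that list was 0.30 and its mean −0.33. Among genes of epithelial-mesenchymal transition, 3 of 6 rose and 3 fell (adjusted p = 0.93, median −0.24, mean 0.29). Mmp14 and Vim rose, Vim to only 13.2 ± 2.0 CPM, and Cdh2 and Fn1, which encode N-cadherin and fibronectin, fell by 2.13 and 1.71 on the log2 scale.

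Of 15 epithelial junction genes, 7 fell and 5 rose (adjusted p = 0.507). Adjusted over the list alone, 13 passed. The claudin genes moved apart, Cldn18 down as given above and Cldn3 up from 3.58 ± 0.75 to 67.2 ± 6.4 CPM, and Krt8, Esrp2 and Ocln fell 1.66-fold, 1.69-fold and 1.62-fold. Among 18 genes of the actin cytoskeleton and focal adhesions, 10 fell and 3 rose (adjusted p = 0.232). Actn1 (331.7 ± 34.9 to 128.8 ± 6.5 CPM) and Tagln2 fell, and Tpm2 (17.0 ± 2.5 to 77.4 ± 6.8 CPM) and Cnn2 rose. The unfolded protein and stress list had 6 lower and 2 higher of 12 (adjusted p = 0.318), 9 of them past the threshold adjusted over the list alone. Atf3 fell from 28.6 ± 2.8 to 7.76 ± 1.75 CPM and Asns fell from 182.3 ± 16.9 to 113.7 ± 4.5 CPM, while the heat shock genes Hspa1a and Hspa1b, which are nearly identical copies, rose 2.31-fold and 1.89-fold. Of 10 immediate early genes, 4 fell, including Jun (47.8 ± 5.0 to 19.4 ± 1.9 CPM), Ier3 and Fosl1, and 2 rose, including Egr1 (adjusted p = 0.605). Of 13 interferon response genes, 4 fell and 1 rose (adjusted p = 0.574), and 4 passed adjusted over the list alone. Ifit2 rose 1.81-fold, and Ddx58, Mx1 and Oas1a fell, Oas1a from 6.35 ± 4.72 to 1.18 ± 0.72 CPM. Ddx58 no longer passed without control 4 (adjusted p = 0.0606, edgeR), and Oas1a did not pass by limma-voom (adjusted p = 0.0517, and 0.0606 with quality weights) or without a filter on low counts (adjusted p = 0.0576, edgeR). Mx1 and Oas1a, with adjusted p of 0.0129 and 0.0158 by edgeR, did not pass a threshold of 0.01. Cholesterol synthesis genes divided into 7 higher and 6 lower of 16 (adjusted p = 0.75), with Hmgcs1 and Dhcr7 up 1.49-fold and 1.66-fold and Insig1 and Fdft1 down 2.01-fold and 1.46-fold.

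Markers of other cell types were mostly low in both groups. The most abundant mesenchymal marker, Tagln, was at 1.08 ± 0.36 CPM in controls and 0.76 ± 0.31 CPM in YAP5SA and did not pass the test. Egfl7, with the highest mean over all libraries of the 4 tested endothelial genes, was at 7.67 ± 1.18 and 7.89 ± 1.10 CPM, and of the others 1 rose (Tie1) and 1 fell (Tek, from 8.88 ± 2.98 to 0.32 ± 0.26 CPM), with no call by camera (adjusted p = 0.93, median −0.05, mean 0.03). The immune marker Cd68, a lysosomal protein that epithelial cells can also express, fell from 28.6 ± 8.0 to 7.88 ± 1.15 CPM, and Csf1r rose to 1.49 ± 0.60 from 0.19 ± 0.07 CPM. Of the enteric neural markers Ret and Uchl1 fell, Ret from 7.36 ± 2.0 to 3.17 ± 0.38 CPM. Among 5 mesothelial markers, 2 fell and 2 rose (camera adjusted p = 0.838). Msln (3246 ± 208 to 1441 ± 140.5 CPM) and Krt19 (2543 ± 99 to 2155 ± 83 CPM), which epithelial cells also express, fell, and Upk3b and Lrrn4 rose, Lrrn4 at an adjusted p of 0.0109 (edgeR) that did not pass the stricter threshold of 0.01. No erythroid or pancreatic acinar gene had enough counts to test. Alas2 was at 0.12 ± 0.05 and 0.34 ± 0.22 CPM, and Prss2 at 0.17 ± 0.15 and 0.15 ± 0.29 CPM.

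Apart from the lists for which a separate count is given, the same number of members passed adjusted over the list alone as over all genes tested. None of the 7 list calls made by camera with its preset correlation held with an estimated correlation, while the counts of single genes do not depend on that choice.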

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

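All tests of explanations in this part were chosen after the result they address had been seen. A library was far from the other 3 of its group in 12 of 260 group values examined, where chance alone would give about 13, and the values of these ratios (the gap to the nearest library over the range of the group) are given here without explanation. Among control values, Ddx3y had a ratio of 1 because control 2 held all of its counts (0.325 CPM), and Cdhr2 had 0.835 with control 2 lowest (23.8 CPM). Sec16b (0.89) and Cldn3 (0.892) stood apart in control 1, at 23.6 and 2.46 CPM, and Skil (0.877) and Vim (0.891) in control 4, at 38.5 and 9.98 CPM. Among YAP5SA values, Cdhr2 and Clps (both 1) were counted only in YAP5SA 2, at 0.055 and 0.110 CPM, and Prss2 (1) only in YAP5SA 4, at 0.589 CPM. Ddx3y (0.836) was lowest in YAP5SA 3 at 68.2 CPM, Alox5 (0.989) highest in YAP5SA 4 at 0.589 CPM, and Gata5 (0.857) highest in YAP5SA 1 at 0.453 CPM.

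The number of genes changed was set against other groupings of the libraries. Of the 35 splits of the 8 libraries into groups of 4, only 1, the real one, called as many genes, 6899 with the edgeR quasi-likelihood test, while the highest of the other splits called 0 (58 to 1141 genes at an unadjusted p under 0.05). As a share of the splits this is 0.0286, the smallest that 35 splits can give. Every other split mixed libraries of both groups, which puts the group difference into the spread within its groups. Since the libraries of a group may be technical, the splits cannot exclude a chance difference between the source cultures. They also say nothing on whether genotype, sex or the source of the cultures divides the libraries.

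The first pattern concerns sex, since all 4 controls were female by Xist and all 4 YAP5SA libraries male by their Y-linked genes. Pools of embryos of both sexes are argued against, because neither Eif2s3y in a control nor Xist in a YAP5SA library exceeded 0.341% of the other group's mean. If each library came from its own embryo, drawn independently, sexes uniform within both groups would have a chance of 0.0156, which leaves that reading possible but makes a small number of source embryos per genotype a candidate explanation. A sex effect on autosomal genes and the effect of YAP5SA cannot be told apart, because 0 libraries differ in sex from their group, and differences between embryos may add to either. The biological explanation given by the design, YAP5SA, stays open alongside.

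The second pattern is the trace left in YAP5SA libraries of 9 autosomal genes above 200 CPM in controls and under 1% of that in YAP5SA (Cldn18, Pgc, Cym, Anxa10, Apob, Cybrd1, Gkn3, Kcnj15 and Ndnf), whose median remaining share was 0.287%, 0.370%, 0.230% and 0.0503% in YAP5SA 1 to 4, beside 0.144%, 0.341%, 0.143% and 0.0508% for Xist, which male cells should lack. If the traces were reads carried over from control libraries, the median should match Xist, and it lay within the 95% Poisson interval of the Xist share in 2 of the 4 libraries (YAP5SA 2 and 4) and above it in the others. Reads carried over from control libraries as the whole of Ndnf are argued against, since 0.479%, 1.13%, 0.765% and 0.528% of it remained and the lower Poisson limit of this share lay above the upper limit for Xist in 4 of the 4 libraries. For the genes other than Ndnf, the median lay within the Xist interval in 3 of the 4 libraries (above it in YAP5SA 1), while the lower limits of Cybrd1 in YAP5SA 1 (0.237%) and Gkn3 in YAP5SA 4 (0.141%) also lay above the upper limits for Xist there (0.227% and 0.105%), so that carry-over and a low true expression in rare cells cannot be told apart and both may contribute. To the extent that carry-over does, the folds of the most reduced genes understate the difference.

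The third pattern is the loss of gastric genes, for which a culture of another foregut or gut epithelium could be a simple explanation. Forestomach squamous epithelium is argued against by its basal layer genes Krt5, Krt14, Trp63, Dsc3 and Col17a1 and by the suprabasal keratin gene Krt1. Their highest mean in YAP5SA was 0.0308 CPM (Krt1). The median over the whole fixed list of 17 genes was 0.563 CPM (0.531 CPM in controls). Such a median cannot decide for any of the tissues considered here. Gastric list members such as Atp4b (0.05 CPM) and Lipf (0.19 CPM) were nearly absent from the hindstomach controls as well. On the other side, Krt4, Sprr3 and Krt6a rose, as did the anterior foregut or stratified epithelium factors Irx2 (9.97 to 93.1 CPM), Pax9 (7.79 to 35.9 CPM), Tfap2a (0.36 to 11.4 CPM), Eya1, Klf4 and Sox2. These factors come from a list written after the first results. In that list Sox21 did not pass the test (47 CPM in controls and 47.1 CPM in YAP5SA), and Foxe1 was too low to test. Intestinal epithelium is argued against by Cdx1, Cdx2, Fabp1, Fabp2, Olfm4, Tff3, Atoh1 and Cdh17, at most 0.566 CPM (Fabp2). However, Krt20 (16.6 to 94.9 CPM) and Muc2 (log2 fold change 1.55) rose, and Vil1 was still at 12.2 CPM. The median over the whole fixed list of 21 genes was 0 CPM (0.0677 CPM in controls). Lung or airway epithelium is argued against by Nkx2-1, Scgb1a1, Scgb3a2 and Sftpc, at most 0.125 CPM. The median over the whole list of 10 genes was 0.0216 CPM (0.0308 CPM in controls). Cyp2f2 of that list rose, however, while the other members were at most 0.732 CPM (Foxj1). What remains open is a change of state under YAP5SA, a difference in sex or source embryo, or an epithelium that none of these markers covers.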

How the results depend on the processing

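The alternative that left out X- and Y-linked genes was added after the data were examined and all others were planned. Under every normalization, filter, test and threshold tried, the counts of genes changed, higher, lower and changed at least 2-fold stayed within 1.5 times those reported; genes changed ran from 5377 (adjusted p under 0.01) to 7611 (no filter), with 6858 by DESeq2, 6955 by limma-voom and 6660 without X- and Y-linked genes, and without 1 library from 6371 to 7317. Between 77.9% and 99.9% of the 6899 genes were called again, always in the same direction. The sample number as a block gave 6586 genes. Deviations of same-numbered libraries correlated at −0.055, −0.079, 0.094 and 0.038, and those of the other pairs at −0.182 to 0.145. These correlations show no pairing by number but cannot exclude a weak one, and the labels do not say whether equal numbers share a source. The calls for lists depend on the set test, and with an estimated correlation 0 of the 27 lists were called. The estimated correlation of the pit cell list was −0.0508, under the preset 0.01, so a higher correlation did not remove that call. What removed the calls was not tested. Fry, which tests the lists on their own, called 17, among them the YAP/TAZ targets (higher, adjusted p = 0.0231 by fry). The list: gastric stem and progenitor cells, not called by camera (adjusted p = 0.93), was lower by fry (adjusted p = 1.26e-05); the cause was not tested. The list: gastric epithelial transcription factors, not called, was called by camera with library size alone (adjusted p = 0.0415) and with the block (0.0442). The first principal component held 85.5% with all tested genes, 98.7% with 100 genes and 97.0% to 97.5% without 1 library. For the named genes, 2297 comparisons kept direction and side of the threshold, 11 fell short of it (Oas1a, Ltc4s, Mx1, Lrrn4 and Ddx58), 2 passed it (Ccn1), and 0 reversed. Depth limits genes with few counts: means under 0.1 CPM rest on a handful of reads.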

Other observations

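The genes in this part were chosen after their values were seen, and no explanation is tested for them. A list of 8 transcription factors known from anterior foregut or stratified epithelium, written after the first results, held 7 genes with enough counts to test, of which 6 rose in YAP5SA and Sox21 (47.0 CPM in controls and 47.1 CPM in YAP5SA) did not pass the test. Irx2 rose from 9.97 ± 2.56 to 93.1 ± 3.5 CPM, Eya1 from 3.46 ± 0.44 to 42.3 ± 2.6 CPM, Pax9, a pharyngeal and oesophageal factor, from 7.79 ± 0.41 to 35.9 ± 1.5 CPM, Tfap2a from 0.36 ± 0.18 to 11.4 ± 0.8 CPM and Sox2, required for foregut identity, from 30.6 ± 1.7 to 47.6 ± 4.3 CPM. Klf4, given above, was the last of the 6 (Klf4 and Sox2 are also in lists fixed beforehand), and Foxe1 was at 0 CPM in controls and 0.93 ± 0.51 CPM in YAP5SA. The adjusted p of the 6 lay between 5.90e-16 and 1.87e-06 (edgeR quasi-likelihood with Benjamini-Hochberg adjustment).

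Large increases outside the fixed lists included Gabrp, a subunit of the GABA type A receptor found in several epithelia, from 173.5 ± 18.9 to 1657 ± 37 CPM, Pcolce, a procollagen processing enhancer, from 19 ± 1.7 to 217.7 ± 17.6 CPM, Khdc1a from 6.22 ± 1.56 to 221.2 ± 19 CPM, the axon guidance gene Sema3a (log2 fold change 5.67) and Lbp, which encodes lipopolysaccharide-binding protein, from 2.68 ± 0.19 to 105.9 ± 4.9 CPM. Large decreases included Anxa10, a gastric annexin (396.5 ± 34.7 to 0.91 ± 0.61 CPM), Apob (259.1 ± 68.3 to 0.64 ± 0.26 CPM), Rdh10, a retinol dehydrogenase that makes retinal for retinoic acid synthesis (737.4 ± 33.7 to 24.8 ± 2.5 CPM), and Agr2 (40.1 ± 6.5 to 1.13 ± 0.25 CPM).

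Kdm6a, Kdm5c, Eif2s3x and Ddx3x, the only genes known to escape X inactivation that were examined, were lower in YAP5SA, in which Xist was nearly absent. Their log2 fold changes were −0.44, −0.63, −0.72 and −0.33. The water channel gene Aqp1 was higher in each YAP5SA library but unevenly, with 130.9, 81.5, 83.4 and 208.1 CPM in YAP5SA 1 to 4 and 2.14 ± 0.30 CPM in controls. Oas1a was uneven among controls, at 3.35, 3.09, 13.2 and 5.78 CPM in control 1 to 4, and Bst2 was highest in the same library (control 3, 32.3 CPM, with the other controls from 9.10 CPM upward).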
